A study of Mus musculus with 19 samples.

How the data were processed

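RNA was sequenced from the gastrocnemius muscle of mice. Per the labels' protocols, the tumour-bearing mice were male Balb/c mice that had received C26 cells under the skin of the flank at an age of 2 months and, from day 4, intraperitoneal rolipram at 3 mg/kg or vehicle. RNA was extracted from snap-frozen muscle, polyA RNA was enriched on oligo d(T) beads, and libraries were made with a stranded mRNA kit. The groups and sample numbers were taken from the labels: 7 healthy control, 7 C26 vehicle and 5 C26 rolipram libraries, each compared as a single value per gene.

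Per the submitters' processing notes, reads were aligned with STAR 2.5.3a to mm10 and counted with featureCounts 1.6.4. The annotation release, the strand setting of the counting, the tool that made the normalised values and the filter that chose the listed genes were not given in the sources used here. The deposited table holds RPKM (reads per kilobase of gene per M, or mega, reads) computed by the authors, for 13067 gene symbols in 19 columns, 1 per library. No value was 0. In 40 genes the lowest value was shared exactly by at least 2 libraries, at 0.01019 reads per M reads, as a prior of about 0.25 read for genes with no read would give. The library sizes, which the table does not list, were recovered from the spacing of the low values of these genes above that floor: with sizes of 17.06 to 46.84 M reads, 100% of the low values checked were whole numbers of reads within a tolerance of 0.05 read. These sizes are estimates from the deposited values and not counts of sequenced reads.

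Values were analysed as log2(RPKM + 1). Genes with an RPKM of at least 1 in at least 5 libraries were kept, which left 11141. A linear model of the 3 groups was fitted over all 19 libraries in limma 3.58.1 (R 4.3.3), with variance moderation that followed the expression trend and was robust to outlying genes, and the 3 differences between groups were tested two-sided. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and an adjusted p below 0.05 was called. RPKM is not a count, so no count model was used. A log2 change on this scale is compressed for genes near or below 1 RPKM. Fitting the same model to simulated data with known changes recovered, for C26 vehicle against control, 62.7% of changes of 0.5, 95.5% of 1 and 100% of 2 on the log2 scale, with 8 unchanged genes called of 10833 genes in step. For C26 rolipram against C26 vehicle the shares were 52.2%, 89.6% and 100%, with 14 called of 10849. For C26 rolipram against control they were 62.7%, 94% and 100%, with 4 called of 10853. False calls made up 4.44% of calls for C26 vehicle against control and 2.29% for C26 rolipram against control. For C26 rolipram against C26 vehicle they made up 8%, above the threshold of 0.05. The simulated noise was drawn independently for each gene, with 1 SD per gene for all groups. Changes of each size were planted in only 66 or 67 genes, all with a control mean above 2 on the log2 scale. Many more genes were called in the real data, where the adjustment over all genes is then less strict. Real libraries can also vary in many genes together. These shares and false calls therefore hold only for few changed genes and independent noise.

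A set of 38 gene lists with 653 member entries, covering pathways of muscle wasting, mitochondria and cyclic AMP signalling and markers of the cell types of whole muscle, was fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. Lists with at least 3 kept members (35 lists) were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison. As alternatives, camera estimated the correlation and fry tested each list by itself, without comparing it with other genes. Members were counted as higher, lower or not passing over all genes and again with p-values adjusted over the list alone. A list score per library was the mean over members of log2(RPKM + 1) minus the control mean, and group differences were tested by exact permutation, two-sided, over 3432 assignments for 7 against 7 libraries and 792 for 7 against 5. The smallest p these tests gave was 0.000583, 0.00253 and 0.00126 in the 3 comparisons. Like fry, these tests did not subtract the change of all genes. Some genes belong to more than 1 list, such as Pde4b and Pde4d, which are in both cyclic AMP lists.

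Genes named in the text were, by that rule, a fixed panel of 18 genes, the 8 largest rises and 8 largest falls per comparison among called genes whose libraries did not overlap between groups, with predicted genes left out, and for each list the members with the smallest p: 2 in the majority direction and 1 in the other. Listed examples were mostly genes whose call survived the removal of any single library. Of 315 results for genes chosen by the rule, 27 lost their call when a single library was left out, not all of them marked in the text. The 315 include panel genes that were not called and had no call to lose. The result of 1 gene that the rule names is not reported here. Of the panel, Fgf21 was not in the table. Cpt1b was below the filter, at 0.283, 0.313 and 0.523 RPKM in control, C26 vehicle and C26 rolipram, with 81.4% of its exonic sequence shared with another gene on the same strand, so it was not tested and its low values were not read as low expression. Coordinates came from GENCODE M21 on GRCm38, in which 13006 of the 13067 symbols (99.53%) were found. Of 207 named genes, 73 overlapped exons of another gene, and for 1 of them on the same strand and 3 on the opposite strand at least 50% of the exonic sequence was covered.

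Alternatives recomputed the gene counts and the named genes with pseudocounts of 0.1 and 5, without the filter, with a filter of mean RPKM of at least 5, with median-of-ratios scaling, with quantile normalisation, with each pair of groups fitted alone, without trend and robust moderation, with array weights, with the sample number as a replicate block, and without each library in turn. The list tests were repeated with an estimated correlation, with fry, with median-of-ratios scaling and with the replicate block only. A pair of further alternatives was chosen after the data had been seen: without the 4 libraries of over 29 M reads, and without the libraries numbered 7. The reversal of tumour changes was set beside 100 simulated data sets with no effect and 100 splits of the vehicle libraries; simulations of these splits, and simulations with the tumour effect kept and no rolipram effect, were added after the data had been seen (100 draws each). Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Sequencing batches were not given in the sources used here, and no library had values identical to another. Raw reads were not analysed here.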

Results

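Messenger RNA was measured by polyA-selected, stranded RNA sequencing in 19 libraries of gastrocnemius, a fast calf muscle of the mouse. The libraries fell into 3 groups: 7 from healthy control mice, 7 from mice carrying a subcutaneous tumour of C26 cells and given vehicle, and 5 from C26 mice given rolipram. C26 is a mouse colon adenocarcinoma line whose tumours cause cachexia, the wasting of muscle and fat during cancer. Rolipram blocks phosphodiesterase 4, the enzyme family that breaks down the second messenger cyclic AMP, and was injected at 3 mg/kg from day 4 after the tumour cells. The labels number the samples but do not say that each came from a separate animal, so p-values measure the spread between these samples. The library sizes recovered from the deposited values were 20.6 ± 1.94 M (mega) reads in controls (SD, n = 7), 27.4 ± 9.55 M in C26 vehicle (n = 7) and 26.01 ± 9.15 M in C26 rolipram (n = 5), and ran from 17.06 to 46.84 M over all libraries. Of 13067 genes in the table, 11141 were tested. The first principal component held 66.8% of the variance and set all controls (mean -47.1) apart from C26 vehicle (33.1) and C26 rolipram (19.6). The second held 8.49% and separated C26 rolipram (-18.9) from C26 vehicle (10.4).

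**Figure D1:**
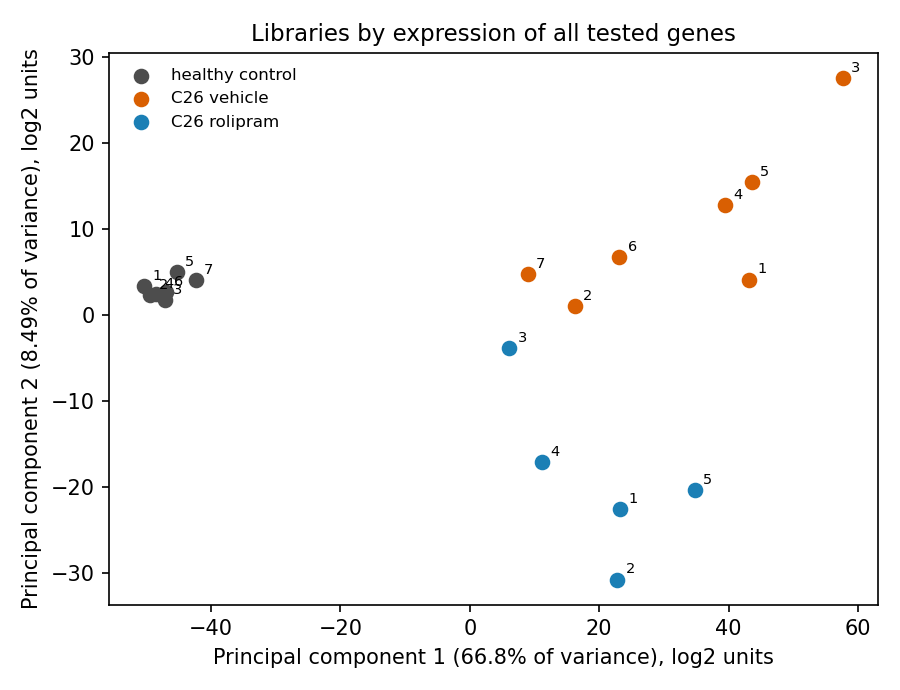
Each point is 1 library, numbered by replicate, placed by its first (horizontal) and second (vertical) principal component of log2(RPKM + 1), with colours for the 3 groups. Controls averaged -47.1 on the first axis against 33.1 for C26 vehicle and 19.6 for C26 rolipram, and all 5 rolipram libraries lie below every other library on the second.

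The first comparison, C26 vehicle against healthy control, set the muscle of vehicle-treated tumour-bearing mice against healthy muscle. A treatment start and an age were recorded for the C26 mice and not for the controls. Sex and strain are likewise stated above only for the tumour-bearing mice. Changes described as occurring with the tumour therefore cannot be told apart from effects of vehicle injection or of a difference in these traits. The muscle of tumour-bearing mice raised genes for protein breakdown and acute inflammation. It lowered genes for energy metabolism, fast contractile proteins and connective tissue matrix. Single genes of the cyclic AMP pathway named in the series title changed in both directions, but camera called neither cyclic AMP list. The PDE4 family split, and of 25 targets of the cyclic AMP response factor CREB 12 were higher and 3 lower. These counts are to be read against the shares of all genes, given next. Of the 11141 genes tested, 4822 (43.3%) were higher and 2646 (23.8%) lower at an adjusted p below 0.05, among them 993 higher and 524 lower by at least 2-fold. For 4353 genes (39.1%) no vehicle library overlapped any control library, against a chance share of 0.0583%. The median change of all genes was 0.15 on the log2 scale in both comparisons with controls and -0.01 between C26 rolipram and C26 vehicle. The most abundant transcripts took a smaller share of the reads with the tumour: the 20 largest held 45.0% of all RPKM in controls, 32.4% in C26 vehicle and 32.0% in C26 rolipram. The share of calls that were higher was 64.6% as deposited and 50.6% after median-of-ratios scaling. Medians of gene lists are therefore given relative to the median of all genes of the comparison, and changes of single genes as deposited. Of 35 gene lists tested, the camera test with a preset correlation called 7 higher and 13 lower. No list passed in any comparison when camera estimated the correlation between the genes of a list from these libraries, where 2 lists had an unadjusted p below 0.05 in this comparison, while 25 lists passed by fry. In exact permutation tests of list scores, 26 lists passed, including all 20 called by camera.

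Muscle protein is broken down in atrophy mainly by the ubiquitin-proteasome system and by autophagy, and both programmes rose with the tumour. Trim63, which encodes the muscle ubiquitin ligase MuRF1 that tags myofibrillar proteins (GRCm38 chromosome 4, 134315120 to 134329629), rose from 116 ± 22.4 to 2589 ± 810 RPKM (SD, n = 7 each), a log2 change of 4.42 (SE 0.19, adjusted p = 1.47e-13). Fbxo32, which encodes atrogin-1, the other hallmark ligase of atrophy, rose from 38.4 ± 10.8 to 744 ± 208 RPKM, a log2 change of 4.24 (adjusted p = 3.53e-13). In both genes all 7 vehicle libraries lay above all 7 controls. Foxo1, a transcription factor that drives both ligases, rose by 1.37 (adjusted p = 3.64e-05). Of 28 atrophy genes, 23 were higher, 0 lower and 5 did not pass, with a median change of 1.87 relative to all genes (camera adjusted p = 7.37e-08). All 31 proteasome subunits were higher, with a relative median of 1.19 (adjusted p = 3.52e-12). Examples were the regulatory particle subunits Psmd2, which rose by 2.02, and Psmd1, which rose by 1.46. Of 26 autophagy and lysosome genes, 21 were higher and 1 lower, and the relative median was 0.59 (adjusted p = 6.57e-05). Map1lc3b, which coats the autophagosome membrane, rose by 2.29 and the cargo receptor Sqstm1 by 1.93. The 1 lower gene was Fundc1, a receptor for the removal of mitochondria, with a change of -0.66. Adjusted over the list alone, the counts of these 3 lists were the same. The camera calls gave adjusted p = 0.323 with an estimated correlation for atrophy, 0.337 for the proteasome and 0.323 for autophagy.

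Genes of mitochondrial energy production fell together. Of 36 nuclear-encoded subunits of complex I, the entry point of electrons into the respiratory chain, 34 were lower and 1 higher, with a median of -0.89 relative to all genes (camera adjusted p = 6.89e-13). All 4 subunits of complex II were lower (relative median -0.88, adjusted p = 0.00177), as were all 9 of complex III (-0.93, adjusted p = 1.71e-05). In complex IV, which passes electrons to oxygen, 11 of 14 were lower and 1 higher (-0.76, adjusted p = 0.000163). In ATP synthase 15 of 16 were lower and 0 higher (-0.94, adjusted p = 2.67e-07). With an estimated correlation, complexes II and III had an adjusted p = 0.323, complex I and ATP synthase 0.326 and complex IV 0.473. Examples were Ndufs1 of the electron-accepting arm of complex I (-1.28), Sdhd, a membrane anchor of complex II (-1.17), and Cyc1, the cytochrome of complex III (-1.39). Others were the muscle isoform Cox7a1 of complex IV (-1.69) and Atp5a1, a subunit of ATP synthase (-1.04). The 1 higher gene of complex I was Ndufa7 (0.31), whose call was lost under median-of-ratios scaling (adjusted p = 0.312) and quantile normalisation (0.165), and the 1 of complex IV was Cox8a (0.50). All 7 tested mRNAs encoded in the mitochondrial genome were lower (-0.93, adjusted p = 7.15e-05, and 0.323 with an estimated correlation). Among them mt-Cytb changed by -0.78 and mt-Nd2 by -0.97, the latter by only -0.20 after quantile normalisation (adjusted p = 0.204). Of 22 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 17 were lower and 1 higher (-0.76, adjusted p = 8.9e-08, and 0.323 with an estimated correlation). Idh3a, the rate-setting dehydrogenase of the cycle, changed by -1.52, Mpc2, a carrier of pyruvate into mitochondria, by -0.97, and Cs, which encodes citrate synthase, by -0.96 (adjusted p = 4.89e-07). Adjusted over the list alone, the counts of these lists were the same.

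Regulators of mitochondrial gene expression did not move as a block. Esrra, the nuclear receptor that switches on oxidative metabolism genes, fell from 53.5 ± 6.33 to 20.8 ± 4.24 RPKM (n = 7 each), a log2 change of -1.34 (adjusted p = 1.25e-06), with all vehicle libraries below all controls. Tfam, which maintains mitochondrial DNA, fell by 0.53 (adjusted p = 5.25e-06). Ppargc1a, the coactivator PGC-1α, did not differ (-0.06, adjusted p = 0.797), and its relative Pprc1 rose by 0.80. Of 25 genes of mitochondrial biogenesis and dynamics, 8 were higher and 10 lower, or 9 and 10 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.131). Vdac1, the main pore of the outer membrane, fell by 0.79. Mitochondrial ribosomal proteins were lower in 32 of 77 and higher in 14 genes, with a relative median of -0.33 (adjusted p = 0.000709, and 0.594 with an estimated correlation). Mrpl19 of the large subunit fell by 1.02, although 36.0% of its exonic sequence lies under a gene on the opposite strand, and Mrps30 rose by 0.46. Cytosolic ribosomal proteins moved the other way: 72 of 74 were higher and 0 lower, with a relative median of 0.50 (adjusted p = 7.53e-09, and 0.544 with an estimated correlation). Rpl10a rose by 1.35 and Rpl22 by 0.80; reads of such genes can be shared with their many processed pseudogenes. Of 22 genes of glycolysis and glycogen, 13 were lower and 4 higher (-0.78, adjusted p = 0.00157, and 0.367 with an estimated correlation). Pgm1, which links glycogen to glycolysis, changed by -2.42 and Pkm, the last step to pyruvate, by -1.15, whereas Gys1, the muscle glycogen synthase, rose by 0.68. Fatty acid uptake and oxidation genes were mixed, with 9 of 27 higher and 8 lower (adjusted p = 0.615); the mean as deposited was 0.20, the relative median -0.13 and the camera direction down. Pnpla2, the lipase that starts the breakdown of stored triglyceride, rose by 2.10, Eci2, an enzyme for unsaturated fatty acids, rose by 1.06, and Acsl1, which activates fatty acids, fell by 1.02. These last 4 lists had the same counts adjusted over the list alone.

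Within the cyclic AMP pathway, the 4 PDE4 genes split. Pde4a, on GRCm38 chromosome 9 from 21165714 to 21213248, fell from 13.9 ± 1.47 to 1.23 ± 0.875 RPKM (SD, n = 7 each), a log2 change of -2.83 (SE 0.21, adjusted p = 9.99e-10), with all 7 vehicle libraries below all 7 controls. Pde4b rose by 0.97 (adjusted p = 0.0018) and Pde4c by 0.80 (adjusted p = 8.96e-07). Pde4d rose by 0.75 (adjusted p = 0.00427), or by 0.45 after quantile normalisation, which did not pass (adjusted p = 0.0604). Creb1 itself did not pass as deposited (-0.12, adjusted p = 0.311) and was lower after median-of-ratios scaling (-0.25, adjusted p = 0.0192). Of 31 genes of cyclic AMP signalling, 13 were higher and 9 lower, the same when adjusted over the list alone, where 43.3% of all genes were higher and 23.8% lower. Its median was 0.04 as deposited and -0.11 relative to all genes, and the camera direction was down without a call (adjusted p = 0.609). Atf1 (0.97) and Crtc2 (0.99), a CREB relative and a CREB coactivator, were higher. Of 25 CREB target genes, 12 were higher and 3 lower, or 11 and 2 adjusted over the list alone. Their relative median of 0.34 was not called by camera (adjusted p = 0.609). The list score was higher in C26 vehicle by an exact permutation test (adjusted p = 0.00102), which does not subtract the shift of all genes. The immediate early genes Junb (2.94) and Maff (2.35), which many stimuli induce, rose, and Id2, an inhibitor of differentiation factors, fell by 0.49. Nr4a1, an orphan nuclear receptor induced by cyclic AMP, did not differ (0.01, adjusted p = 0.96).

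Contractile genes of fast fibres fell. Of 16 fast sarcomere genes, 11 were lower and 1 higher (relative median -1.06, camera adjusted p = 0.000264, and 0.384 with an estimated correlation). Myl1, a light chain of fast myosin, fell by 1.80, and Mylk2, the kinase that phosphorylates fast myosin light chains, rose by 1.24. Myh4, the heavy chain of type IIb fibres and the most abundant myosin here, changed by -0.97 (adjusted p = 5.42e-05), or by -0.13 after quantile normalisation (adjusted p = 0.577). Of 13 slow sarcomere genes, 4 were lower and 0 higher, or 3 and 0 adjusted over the list alone. Their relative median was -0.42 (adjusted p = 0.0461, and 0.594 with an estimated correlation), and the call was lost under median-of-ratios scaling (adjusted p = 0.0724). The slow light chains Myl3 and Myl2 changed by -1.11 and -1.02, and Myh7, the slow myosin heavy chain, did not pass (-0.41, adjusted p = 0.318). Of 19 genes of the common sarcomere and excitation, 6 were lower and 4 higher (adjusted p = 0.163). Jph2, which holds calcium stores next to the surface membrane, fell by 2.32, the voltage sensor Cacna1s fell by 1.14, and Des, the intermediate filament desmin, rose by 1.22. The fast and common lists had the same counts adjusted over the list alone.

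Inflammatory and hormonal response genes rose. Of 24 genes of the IL-6, STAT3 and NF-κB response, 21 were higher and 2 lower (relative median 1.81, camera adjusted p = 1.5e-06). Socs3, the feedback inhibitor of STAT3, rose by 3.38 (adjusted p = 6.56e-08) and Stat3 itself by 2.14 (adjusted p = 1.49e-14), while the repressor Bcl6 fell by 0.84. All 16 glucocorticoid-responsive genes were higher (2.05, adjusted p = 4.14e-06). Both lists had an adjusted p = 0.323 with an estimated correlation, and their counts adjusted over the list alone were the same. Of 9 macrophage markers, 8 were higher and 0 lower, with a relative median of 1.15 that camera did not call (adjusted p = 0.086) and median-of-ratios scaling did (adjusted p = 0.0236). The complement gene C1qb rose by 1.45 and the scavenger receptor Cd163 by 1.43. All 5 erythroid markers were higher (1.73, adjusted p = 0.00988, and 0.473 with an estimated correlation), including Alas2, the first enzyme of haem synthesis in red cells (2.20), and the globin Hbb-bs (2.23), whose reads can be shared with near-identical globin genes. Connective tissue genes moved down: of 16 fibroblast and matrix markers, 13 were lower and 1 higher (-1.20, adjusted p = 8.26e-05, and 0.48 with an estimated correlation). The fibrillar collagen Col1a1 changed by -2.50 and the microfibril collagen Col6a2 by -1.78, while Pi16, a surface marker of fibroblasts, rose by 1.02. Of 6 tendon markers, 5 were lower and 0 higher (-1.95, adjusted p = 0.000264, and 0.323 with an estimated correlation), led by Tnmd (-3.05) and the matrix proteoglycan Kera (-2.64). All 4 cell-type lists had the same counts adjusted over the list alone.

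The 8 largest rises and 8 largest falls held members of these lists beside genes of other functions. Mt2 gave the largest change of both the atrophy and the glucocorticoid list (8.07), and Lcn2 that of the IL-6, STAT3 and NF-κB list (7.59). The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose by 8.07 (SE 0.30, adjusted p = 2.44e-14) and 7.38. Mt2 went from 13.4 ± 8.87 to 3334 ± 658 RPKM (n = 7 each), with 73.5% of its exonic sequence under a gene on the opposite strand. Lcn2, an iron-carrier-binding protein of the acute phase, rose by 7.59 (adjusted p = 1.14e-10) and the protease inhibitor Serpina3n by 5.97, the latter within a family of close relatives. Slc39a14, a zinc importer, rose by 4.36, Mustn1, a small nuclear protein of regenerating muscle, by 4.34, and Cnksr1, a scaffold of Ras signalling, by 4.31, beside Trim63. Nmrk2, the muscle kinase that makes NAD from nicotinamide riboside (GRCm38 chromosome 10, 81198170 to 81202051), fell from 149 ± 51.4 to 3.33 ± 2.3 RPKM (n = 7 each), a log2 change of -5.26 (SE 0.32, adjusted p = 5.16e-11). Mybph, a myosin-binding protein, fell by 5.01, with 49.9% of its exonic sequence under a gene on the opposite strand. The changes were -4.89 for the membrane protein Tmem233, -4.88 for Mylk4, a kinase of the myosin light chain kinase family, and -4.71 for Nrep, a protein first tied to nerve regeneration. They were -4.52 for Actc1, the actin of heart and developing muscle, -4.49 for Casq1, which stores calcium in fast fibres, and -4.21 for Ky, a sarcomere-linked protein that keeps muscle mass. In each of these 16 genes no vehicle library overlapped a control library.

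**Figure D2:**
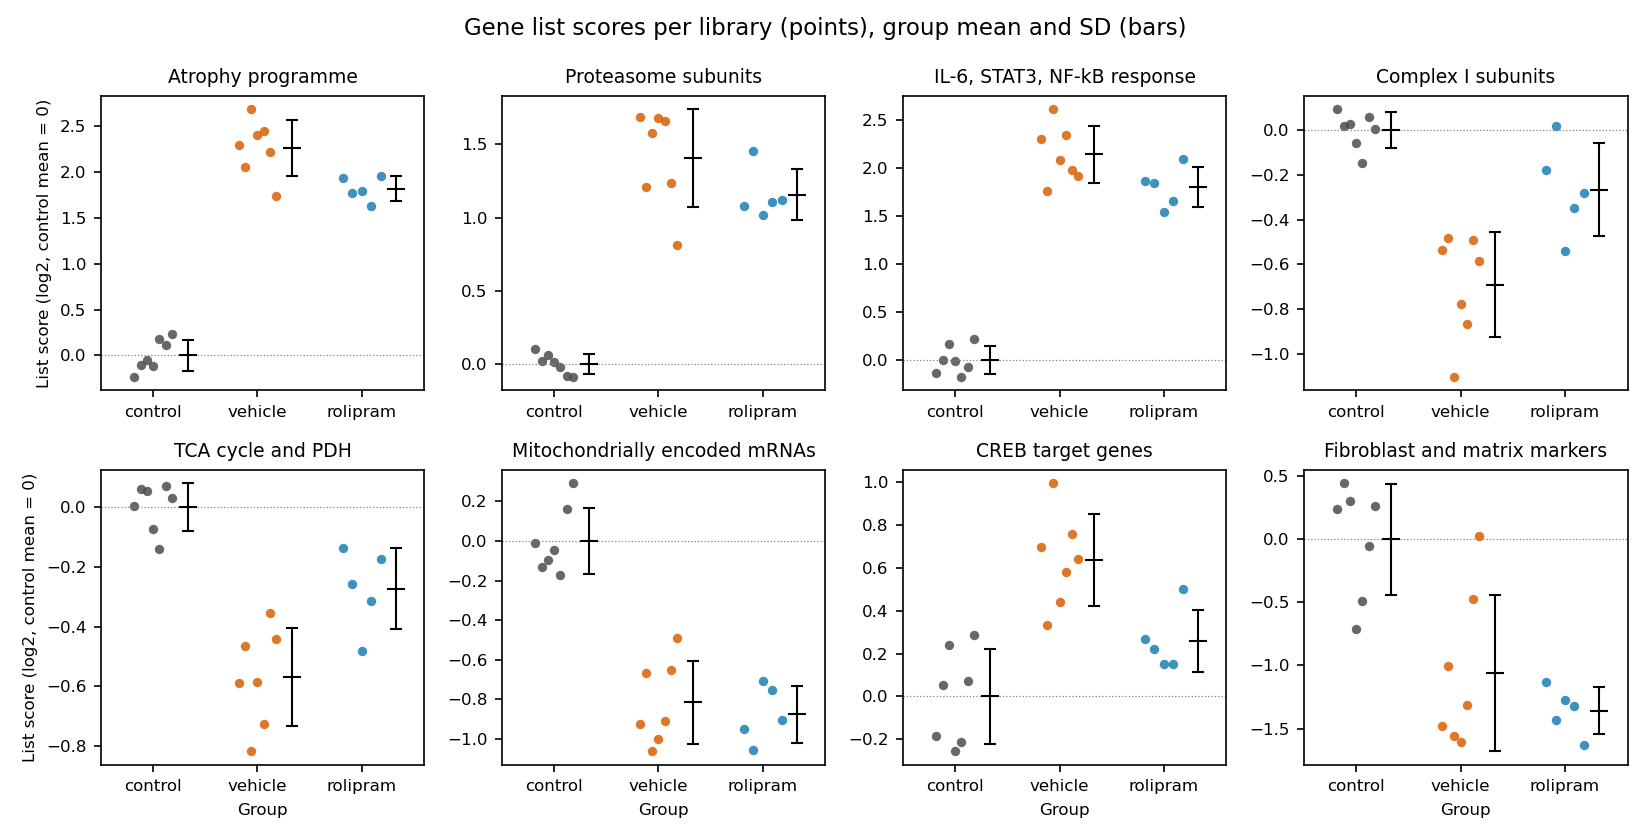
Mean log2 change of the genes of 8 lists in each library (points, vertical axis in log2 units with the control mean at 0) for the 3 groups on the horizontal axis, with bars for group mean and SD. Atrophy scores averaged 2.27 in C26 vehicle and 1.82 in C26 rolipram, complex I scores -0.69 and -0.27, and scores of mitochondrially encoded mRNAs -0.82 and -0.88.

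The second comparison, C26 rolipram against C26 vehicle, asked what inhibition of PDE4 changed in the muscle of tumour-bearing mice. Camera called the lists of nuclear-encoded genes of the respiratory chain, the tricarboxylic acid cycle, glycolysis and the mitochondrial ribosome higher under rolipram, and all but complex IV passed the exact permutation test; in the last 3 of these functions most genes did not pass singly. It called the lists for protein breakdown and for the inflammatory and glucocorticoid responses lower, but none of these passed the exact permutation test, and most of their members did not pass singly. The list of CREB targets was lower by both tests, with 3 of 25 genes called lower. Transcripts encoded in the mitochondrial genome showed no called change. The differences were fewer and smaller than those with the tumour: 1090 genes were higher and 816 lower, 58 and 49 of them by at least 2-fold. For 454 genes (4.08%) no rolipram library overlapped a vehicle library, against a chance share of 0.253%. The counts depended on single libraries, with 665 genes higher without rolipram replicate 1 and 435 lower without rolipram replicate 2. Without rolipram replicate 5 more genes were lower (954) than higher (910). A fit of these 2 groups alone gave 467 higher and 300 lower, and kept 759 of the 1906 calls. The main fit shared 1 estimate of the spread with the controls. Control libraries were more alike, with a lowest pairwise correlation of 0.979, against 0.927 in C26 vehicle and 0.9605 in C26 rolipram. Camera called 10 lists higher and 7 lower. Exact permutation tests of list scores passed for 10 lists, 8 of them also called by camera, all with an adjusted p = 0.0441. With an estimated correlation 0 lists passed, 1 had an unadjusted p below 0.05, and fry passed 13.

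In complex I, 21 of 36 subunits were higher and 0 lower, or 32 and 0 adjusted over the list alone, with a relative median of 0.40 (camera adjusted p = 7.52e-14). Complex II had 2 of 4 higher (3 adjusted over the list alone, median 0.45, adjusted p = 0.00412), complex III 5 of 9 (all 9 adjusted over the list alone, 0.46, adjusted p = 3.43e-05), complex IV 7 of 14 (10 adjusted over the list alone, 0.38, adjusted p = 7.37e-05) and ATP synthase 14 of 16 (all 16 adjusted over the list alone, 0.50, adjusted p = 1.1e-09). None of these complexes had a lower subunit. With an estimated correlation the lists had an adjusted p = 0.379, or 0.491 for complex IV. The exact permutation test passed for complexes I, II and III and for ATP synthase, and not for complex IV (adjusted p = 0.0748). Examples were Ndufb10 (0.93) and Ndufb5 (0.78) of the membrane arm of complex I, Sdhd (0.83), Uqcr10 of complex III (0.60), Cox5a (0.70) and Atp5d (0.70), the last a subunit of the ATP synthase rotor. Mitochondrially encoded mRNAs had 0 of 7 changed, also adjusted over the list alone, and a median of -0.01 (adjusted p = 0.582). Esrra rose from 20.8 ± 4.24 (n = 7) to 41.5 ± 15.3 RPKM (n = 5), a log2 change of 0.91 (SE 0.19, adjusted p = 0.00373), with all 5 rolipram libraries above all 7 vehicle libraries. Ppargc1a (0.29, adjusted p = 0.367), Tfam (0.22, adjusted p = 0.074) and Cs (0.25, adjusted p = 0.176) did not pass; with array weights Tfam (0.24, adjusted p = 0.0173) and Cs (0.32, adjusted p = 0.0295) did. In mitochondrial biogenesis and dynamics 3 of 25 genes were higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.262). Timm23, the import channel of the inner membrane, rose by 0.67. The lower gene was Pprc1 (-0.32), which lost its call without rolipram replicate 2 (adjusted p = 0.0535).

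The lists of the tricarboxylic acid cycle, glycolysis and the mitochondrial ribosome followed the same direction, and the fatty acid list did not move. In the tricarboxylic acid cycle and pyruvate dehydrogenase 9 of 22 genes were higher and 1 lower, or 12 and 1 adjusted over the list alone (median 0.30, adjusted p = 2.72e-05). Idh3a rose by 0.89 and Dlat, the acetyl-transferring core of pyruvate dehydrogenase, by 0.84. In glycolysis and glycogen 9 of 22 were higher and 0 lower, or 12 and 0 adjusted over the list alone (0.47, adjusted p = 4.15e-06), among them Gapdh (0.82). Mitochondrial ribosomal proteins had 28 of 77 higher and 2 lower, or 37 and 2 adjusted over the list alone (0.28, adjusted p = 2.44e-10), such as Mrpl34 (0.86). All 3 lists passed the exact permutation test and had an adjusted p = 0.379 with an estimated correlation. Cytosolic ribosomal proteins had 3 of 74 higher and 0 lower, or 0 of either adjusted over the list alone (0.23, adjusted p = 1.98e-07, 0.656 with an estimated correlation and 0.255 by exact permutation). Fatty acid genes had 1 of 27 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.582). Their median was 0.06 and their mean -0.01 as deposited. The lower gene was Lpl, the lipase that frees fatty acids from lipoproteins, with a change of -1.10.

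Several protein breakdown genes were lower under rolipram while staying above controls, and the evidence for their lists as a whole depended on the test. Trim63 fell from 2589 ± 810 (n = 7) to 1171 ± 290 RPKM (n = 5), a log2 change of -1.11 (SE 0.20, adjusted p = 0.0016), and Fbxo32 from 744 ± 208 to 404 ± 100 RPKM, a change of -0.87 (adjusted p = 0.0078). Foxo1 fell by 0.87 (adjusted p = 0.0263), a call lost when any 1 of 5 libraries was left out, for example rolipram replicate 2 (adjusted p = 0.0842). Of 28 atrophy genes, 10 were lower and 0 higher, or 11 and 0 adjusted over the list alone (median -0.43, camera adjusted p = 1.65e-05, and 0.379 with an estimated correlation). The scores of all 3 breakdown lists missed the threshold in the exact permutation test (adjusted p = 0.0563 for atrophy, 0.252 for the proteasome and 0.117 for autophagy), and fry passed atrophy (adjusted p = 0.0114) but not the proteasome (0.136) or autophagy (0.101). Proteasome subunits had 6 of 31 lower and 0 higher, the same adjusted over the list alone (-0.23, adjusted p = 2.72e-05, and 0.621 with an estimated correlation). Usp14, a ubiquitin-trimming partner of the proteasome, changed by -0.54 and the core subunit Psma1 by -0.49. Autophagy and lysosome genes had 8 of 26 lower and 1 higher, or 9 and 1 adjusted over the list alone (-0.09, adjusted p = 0.0359, and 0.591 with an estimated correlation). Ctsl, a lysosomal protease, fell by 1.52, and Map1lc3a, a relative of Map1lc3b, rose by 1.22.

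In the cyclic AMP pathway no PDE4 gene passed in the main fit under the drug that inhibits their products: Pde4a was 2.54 ± 1.31 RPKM (n = 5), a log2 change of 0.68 (adjusted p = 0.0525), Pde4b -0.50 (adjusted p = 0.211), Pde4c -0.15 (adjusted p = 0.358) and Pde4d -0.55 (adjusted p = 0.109). Pde4a lay close to the threshold and passed as a rise with a mean RPKM of at least 5 (adjusted p = 0.0462), with quantile normalisation (0.0413) and with array weights (0.86, adjusted p = 0.00341). Creb1 did not pass (-0.06, adjusted p = 0.738). Of 31 genes of cyclic AMP signalling, 4 were higher and 3 lower, or 6 and 3 adjusted over the list alone (adjusted p = 0.785). Bves, a membrane protein that binds cyclic AMP, rose by 0.58 and the adenylyl cyclase Adcy9 fell by 0.67. CREB target genes had 1 of 25 higher and 3 lower, or 1 and 5 adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.0281, and 0.379 with an estimated correlation; exact permutation adjusted p = 0.0441). Cited2, a coactivator-binding regulator, was the higher one (1.20), a call lost without rolipram replicate 1 (adjusted p = 0.0571). The lower ones were Nr4a1, the kinase gene Sik1, whose call was lost without rolipram replicate 2 (adjusted p = 0.0523), and Irs2 (-0.99), an adaptor of insulin signalling chosen after its values were seen. Nr4a1 fell from 79.5 ± 12.7 (n = 7) to 39.5 ± 13.6 RPKM (n = 5), a log2 change of -1.04 (SE 0.20, adjusted p = 0.00183), with all rolipram libraries below all vehicle libraries.

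Few fast or slow contractile genes passed singly, and camera called neither list. The fast list had 1 of 16 higher and 1 lower, or 0 and 1 adjusted over the list alone (relative median -0.08, camera adjusted p = 0.386). The slow list had 0 of 13 called, also adjusted over the list alone. Its relative median was -0.37 (camera adjusted p = 0.142), so a fall of slow genes was not excluded. Mylk2 fell by 1.15, to near its control level, while Myh4 (-0.51, adjusted p = 0.069, or -0.70 and 0.00921 with array weights) and Myh7 (-0.92, adjusted p = 0.109) did not pass. The common sarcomere and excitation list had 6 of 19 higher and 2 lower, or 7 and 2 adjusted over the list alone (0.18, camera adjusted p = 0.0437, 0.379 with an estimated correlation and 0.07 by exact permutation). That call was lost under median-of-ratios scaling (adjusted p = 0.0525). Myom2, which ties myosin filaments together at the M-band, rose by 1.07 and Ldb3 of the Z-disc by 1.05. Among response genes, the IL-6, STAT3 and NF-κB list had 8 of 24 lower and 2 higher, or 10 and 2 adjusted over the list alone (-0.39, adjusted p = 0.00127, 0.379 with an estimated correlation and 0.117 by exact permutation). Stat3 fell by 0.58 (adjusted p = 0.000321), Lcn2 rose further by 1.82 (adjusted p = 0.0252), and Socs3 did not pass (-0.39, adjusted p = 0.505). Glucocorticoid-responsive genes had 2 of 16 lower and 0 higher, or 1 and 0 adjusted over the list alone (-0.45, adjusted p = 0.0151, 0.591 with an estimated correlation and 0.117 by exact permutation). Erythroid markers had 1 of 5 lower, or all 5 adjusted over the list alone (-0.65, adjusted p = 0.0153, 0.557 with an estimated correlation and 0.117 by exact permutation). Macrophage (0 of 9, adjusted p = 0.147) and fibroblast markers (0 of 16, adjusted p = 0.0782) showed no changed gene, also adjusted over the list alone. Of 6 tendon markers 1 was higher, the same adjusted over the list alone: Scx, the transcription factor of tendon cells, rose by 1.06 (list adjusted p = 0.592).

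Among genes whose rolipram and vehicle libraries did not overlap, the 8 largest rises were in genes outside these lists. Mylk4 had the largest fitted change of any gene named here, 2.65 (adjusted p = 0.00135), but its libraries overlapped, as did those of Lcn2, so the rule for non-overlapping genes passed both over. Mpp3, a scaffold protein at cell junctions, rose from 0.945 ± 0.467 (n = 7) to 8.89 ± 5.9 RPKM (n = 5), a log2 change of 2.16 (SE 0.26, adjusted p = 6.25e-05), against 8.23 ± 0.463 RPKM in controls. Tbc1d1, a brake on glucose transporter traffic, rose by 2.00 (adjusted p = 0.000602) and Car14, a membrane carbonic anhydrase, by 1.97 (adjusted p = 4.53e-05). Nmrk2 rose from 3.33 ± 2.3 to 14.1 ± 6.17 RPKM, a change of 1.92 (adjusted p = 0.00161). Hr, a nuclear receptor corepressor, rose by 1.82, Ces2c, a carboxylesterase, by 1.52, Sobp, a nuclear zinc finger protein, by 1.49 and Aimp2, a scaffold of transfer RNA synthetases, by 1.40. The largest falls were in Musk, the receptor kinase that organises the neuromuscular junction (-1.60, adjusted p = 0.00128), and Saa2, an acute-phase apolipoprotein with near-identical relatives (-1.59). Fgl2, a secreted fibrinogen-like regulator of immune cells, fell from 15.5 ± 2.96 to 4.73 ± 1.1 RPKM, a change of -1.52 (SE 0.14, adjusted p = 7.15e-06). Slc43a2, an amino acid transporter, changed by -1.45, Zfp36, which destabilises inflammatory mRNAs, by -1.35, and Ulk1, the kinase that starts autophagy, by -1.32. Snhg1, a host transcript of small nucleolar RNAs, changed by -1.45 (adjusted p = 0.0167, or 0.0691 in a fit of these groups alone) and Ranbp9, a scaffold of a ubiquitin ligase, by -1.31 (adjusted p = 0.00904, or 0.05 and not called in a fit of these groups alone). In these 16 genes no rolipram library overlapped a vehicle library.

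**Figure D3:**
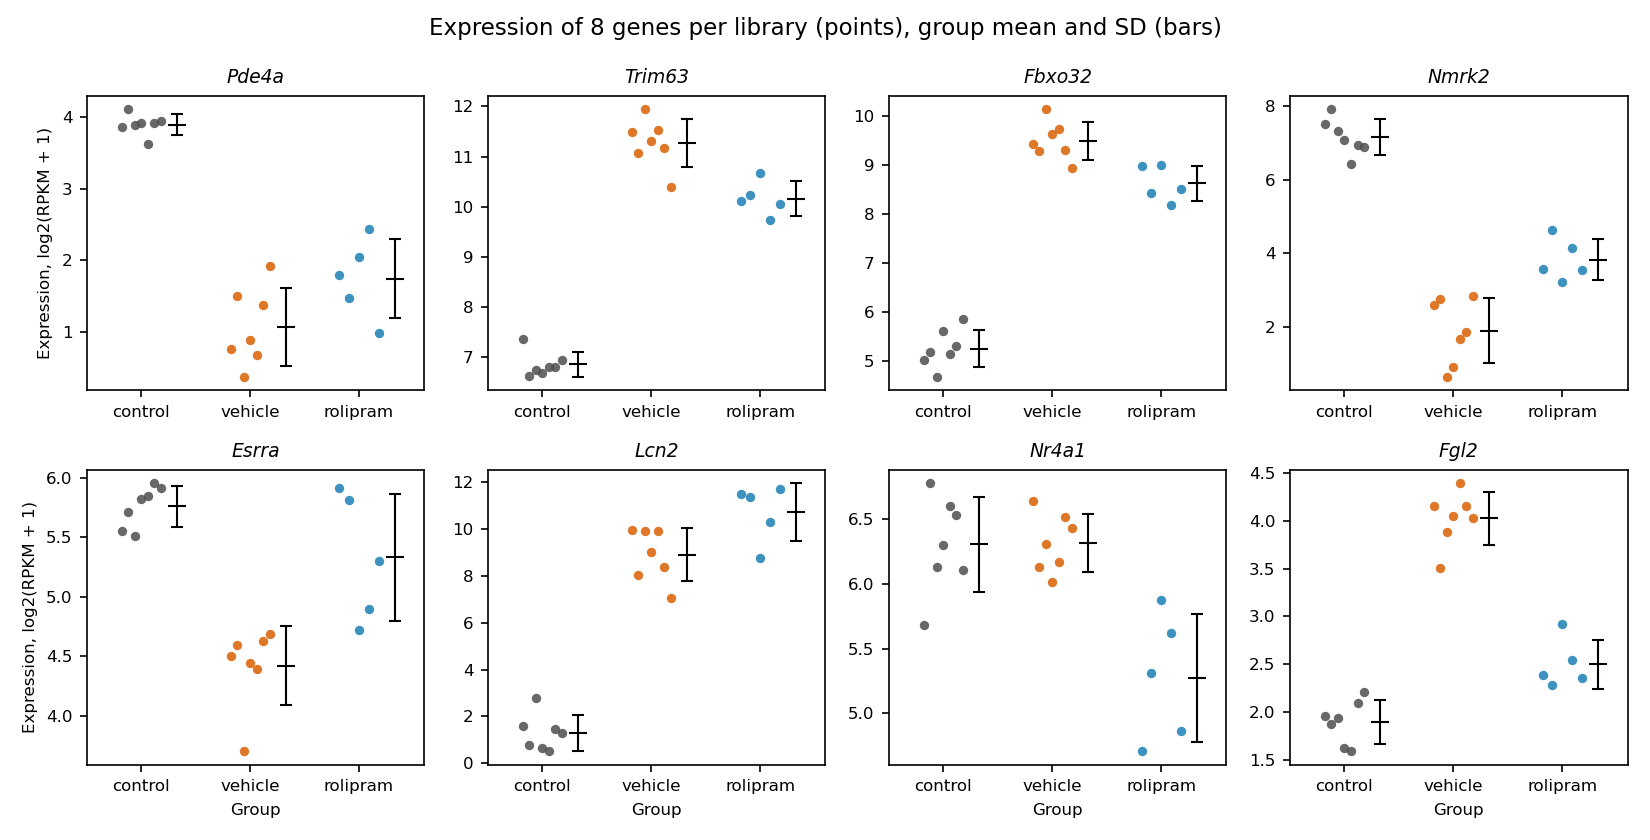
Expression of 8 genes in each library (points, vertical axis log2(RPKM + 1), each panel with its own range) for the 3 groups on the horizontal axis, with bars for group mean and SD. Mean RPKM in control, C26 vehicle and C26 rolipram was 13.9, 1.23 and 2.54 for Pde4a, 53.5, 20.8 and 41.5 for Esrra, and 80.3, 79.5 and 39.5 for Nr4a1.

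The third comparison, C26 rolipram against healthy control, asked how far the muscle of treated tumour-bearing mice stayed from healthy muscle. Genes for protein breakdown, inflammation and the glucocorticoid response stayed high. Mitochondrially encoded, fast contractile, collagen and tendon genes stayed low. Lists of nuclear-encoded respiratory genes had medians below that of all genes by less than in vehicle-treated mice. Complexes II and III were lower by camera, exact permutation and fry, and complexes I and IV and ATP synthase not by all 3. Exact permutation and fry do not subtract the upward shift of all genes (median 0.15), which makes the fall of a list smaller in these tests than in its relative median. The comparison counted 4286 genes higher and 1824 lower, with 711 and 404 of them changed by at least 2-fold. For 3948 genes (35.4%) no rolipram library overlapped a control, against a chance share of 0.253%. The share of calls that were higher was 70.1% as deposited, 49.4% after median-of-ratios scaling and 52.6% after quantile normalisation. Camera called 6 lists higher and 11 lower, exact permutation tests passed for 21, and 15 passed both. With an estimated correlation 0 lists passed, 3 had an unadjusted p below 0.05, and fry passed 20.

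Of the atrophy genes 21 of 28 were higher and 0 lower (relative median 1.05, camera adjusted p = 1.01e-06), and all 31 proteasome subunits were higher (0.94, adjusted p = 5.5e-12), both the same adjusted over the list alone. Autophagy and lysosome genes had 17 of 26 higher and 1 lower, or 19 and 1 adjusted over the list alone (0.50, adjusted p = 0.000216). Trim63 remained higher by 3.31 (adjusted p = 1.16e-10) and Fbxo32 by 3.37 (adjusted p = 1.12e-10), whereas Foxo1 did not pass (0.51, adjusted p = 0.103). The IL-6, STAT3 and NF-κB list had 21 of 24 higher and 2 lower (1.28, adjusted p = 8.84e-06) and the glucocorticoid list 15 of 16 higher (1.40, adjusted p = 1.54e-05), both the same adjusted over the list alone. These 5 lists had an adjusted p = 0.431 with an estimated correlation. Lcn2 had the largest change of the comparison, from 1.83 ± 1.88 (n = 7) to 2098 ± 1209 RPKM (n = 5), or 9.42 on the log2 scale (adjusted p = 3.89e-11), and Socs3 stayed higher by 2.98 (adjusted p = 2.24e-06). Macrophage markers had 5 of 9 higher and 0 lower (0.77, adjusted p = 0.267) and erythroid markers all 5 higher (1.10, adjusted p = 0.051, and 0.0161 after median-of-ratios scaling). Counts adjusted over the list alone were the same for both.

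Complex I had 16 of 36 subunits lower and 2 higher (relative median -0.45, adjusted p = 8.84e-06), complex II 3 of 4 lower, or 4 adjusted over the list alone (-0.48, adjusted p = 0.0375), and complex III 4 of 9 lower, or 3 adjusted over the list alone (-0.44, adjusted p = 0.00451). Complex IV had 2 of 14 lower and 2 higher (-0.34, adjusted p = 0.0375) and ATP synthase 5 of 16 lower and 2 higher (-0.40, adjusted p = 0.00683). With an estimated correlation complexes II and III had an adjusted p = 0.5, complex I 0.637, complex IV 0.705 and ATP synthase 0.663. The exact permutation test passed for complexes I, II and III, and not for complex IV (adjusted p = 0.092) or ATP synthase (0.0682). By fry complexes II and III passed, and complex I (adjusted p = 0.0624), complex IV (0.264) and ATP synthase (0.126) did not. All 7 mitochondrially encoded mRNAs were lower (-1.01, adjusted p = 2.96e-06, and 0.431 with an estimated correlation), and the tricarboxylic acid cycle list had 14 of 22 lower and 0 higher (-0.50, adjusted p = 2.43e-05, and 0.431 with an estimated correlation). Counts adjusted over the list alone were the same for complexes I and IV, ATP synthase and these lists. Esrra did not pass (-0.43, adjusted p = 0.0615), although it did after median-of-ratios scaling (-0.62, adjusted p = 0.0076) and quantile normalisation (-0.73, adjusted p = 0.00239), Cs changed by -0.71 (adjusted p = 9.02e-05) and Tfam by -0.31 (adjusted p = 0.00418). Mitochondrial biogenesis genes had 8 of 25 higher and 8 lower, or 9 and 10 adjusted over the list alone (adjusted p = 0.267). Esrrg, a relative of Esrra, fell by 1.07. Mitochondrial ribosomal proteins had 26 of 77 higher and 14 lower, or 25 and 14 adjusted over the list alone (-0.01, adjusted p = 0.79), and all 74 cytosolic ribosomal proteins were higher, the same adjusted over the list alone (0.72, adjusted p = 1.12e-16, and 0.484 with an estimated correlation). Glycolysis and glycogen had 8 of 22 higher and 8 lower (adjusted p = 0.226), and fatty acid genes 10 of 27 higher and 4 lower (adjusted p = 0.816), both the same adjusted over the list alone. Mean changes as deposited were above 0 while the camera direction was down for fatty acid genes (0.19) and mitochondrial ribosomal proteins (0.12).

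Pde4a stayed lower by this comparison, with a change of -2.15 (adjusted p = 3.23e-07), and Pde4c stayed higher by 0.65 (adjusted p = 5.71e-05), while Pde4b (0.47, adjusted p = 0.151) and Pde4d (0.20, adjusted p = 0.494) did not pass. Cyclic AMP signalling genes had 8 of 31 higher and 4 lower, or 7 and 4 adjusted over the list alone (adjusted p = 0.55), and CREB target genes 5 of 25 higher and 4 lower, or 4 and 3 adjusted over the list alone (adjusted p = 0.587). The CREB list median was 0.11 above that of all genes, with a camera direction of down. Nr4a1 fell by 1.03 from its control level (adjusted p = 0.000165). Fast sarcomere genes had 11 of 16 lower and 1 higher (-0.94, adjusted p = 3.55e-06, and 0.431 with an estimated correlation) and slow sarcomere genes 7 of 13 lower and 1 higher (-0.66, adjusted p = 0.00154, and 0.484 with an estimated correlation). Myh4 changed by -1.47 (adjusted p = 2.31e-06) and Myh7 by -1.34 (adjusted p = 0.00696). Common sarcomere genes had 5 of 19 higher and 3 lower (adjusted p = 0.587). The 3 sarcomere lists had the same counts adjusted over the list alone. Fibroblast and matrix markers had 13 of 16 lower and 0 higher, or 13 and 1 adjusted over the list alone (-1.46, adjusted p = 1.33e-07), and tendon markers 5 of 6 lower, the same adjusted over the list alone (-2.42, adjusted p = 2.66e-05). Both had an adjusted p = 0.431 with an estimated correlation.

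Beside Lcn2, the largest rises were in Mt2 (7.70), Mt1 (6.96), Serpina3n (5.16) and Mustn1 (4.43). Agt, the precursor of angiotensin, rose by 4.22 (adjusted p = 8.49e-06), Eif4ebp1, a repressor of cap-dependent translation, by 3.94, and Fkbp5, a chaperone induced by glucocorticoids, by 3.83. The largest falls were in Nrep (-4.74), Ighm, the heavy chain of immunoglobulin M (-4.57), Myoz3, a Z-disc protein that binds calcineurin (-4.23), Tmem233 (-4.10), Ostn, a secreted muscle peptide (-4.02), Actc1 (-3.75), Mettl21c, a protein lysine methyltransferase of muscle (-3.61), and Casq1 (-3.50). In these 16 genes no rolipram library overlapped a control library.

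Set against each other, the tumour and rolipram changes mostly had opposite signs, which shared vehicle libraries also give when nothing has changed. Of 7468 genes called with the tumour, 74.0% changed in the opposite direction under rolipram, where simulated data with no effect gave a median of 76.4% (range 38.5 to 97.8 over 100 draws). When the vehicle libraries were split so that each comparison used different ones, the median was 74.7% (53.4 to 82.3 over 100 splits). The same splits of simulated data with no effect gave 46.4% (8.998 to 88.4), and 8 of 100 draws reached 74.7%. With the tumour effect kept and no rolipram effect, the simulated medians were 49.45% for shared libraries, with 10 of 100 draws reaching the observed share, and 54.0% for splits, with 11 of 100 reaching 74.7%. The share found in the splits did not need shared values, although the choice of genes was still shared. Variation between libraries that moved many genes together also gave a share as high in some draws. The covariance of both changes across genes was -0.1215 with all libraries and had a median of -0.122 in the splits (-0.1745 to 0.0166). With no effect the simulated covariance was -0.0105 for shared libraries (-0.0909 to 0.00254) and near 0 for splits (-0.0687 to 0.0719), so neither range reached the observed values. With the tumour effect kept, 1 of 100 draws with shared libraries and 5 of 100 with splits were as low. The correlation was -0.509 with all libraries, against a simulated median of -0.562 with no effect, and -0.486 in the splits (-0.61 to 0.0592), which 9 of 100 splits of simulated data with no effect reached. Genes called in both comparisons were 749 up with the tumour and down under rolipram, 624 down and then up, 148 up in both and 10 down in both, where independent lists of these sizes would share 353, 259, 472 and 194. Those expected numbers leave out the shared vehicle libraries, which also favour opposite signs, so the difference from them does not measure a rolipram effect. Called under rolipram and not with the tumour were 318 higher and 57 lower genes.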

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

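Both tests on fibroblast and matrix genes were chosen only after the result was seen, as was the removal of the 4 deepest libraries. The requirement that the depth test on respiratory genes exceed its standard error was also added after its value was known. Libraries that stood far from the rest of their group were sought among the list scores and the 151 genes the text names, by the gap to the nearest library as a share of the group's range. Of 579 groups tested, 27 had such a library, and chance flags about 1 in 20 groups, or 29 here. The most in any library was 5, in rolipram replicate 3.

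Among list scores, rolipram replicate 5 was lowest for glycolysis (gap share 0.72), rolipram replicate 2 highest for the proteasome (0.761) and control replicate 7 highest for interferon-stimulated genes (0.581). Schwann cell markers were highest in vehicle replicate 7 (0.665) and rolipram replicate 3 (0.918). Among genes in controls, the isolated libraries were replicate 5 for Psmd2 (0.599) and Foxo1 (0.692), replicate 2 for Saa2 (0.708), Sdc4 (0.689) and Chrdl2 (0.641), replicate 1 for Uqcr10 (0.651) and replicate 7 for H2-K1 (0.68), all on the high side. In C26 vehicle they were replicate 3, low for Esrra (0.7), replicate 1, high for Ndufa7 (0.583) and low for Adcy9 (0.583) and Cry1 (0.797), replicate 7, low for Psma1 (0.584), and replicate 6, high for Ighm (0.83) and H2-K1 (0.593). In C26 rolipram they were replicate 5, low for Mylk4 (0.859) and high for Sdc4 (0.859) and Cry1 (0.754), replicate 4, low for Map1lc3b (0.718), and replicate 3, low for Des (0.727), Hr (0.739) and Chrnb1 (0.766) and high for S100b (0.741), a Schwann cell gene in the list with the same isolated library. The number stayed at the level of chance, and no explanation was tested for single libraries.

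The gene counts were set against other divisions of the same libraries into groups of the same sizes, with 100 divisions including the real one. For vehicle against control, 1 of the 100 called as many genes, the real one with 7468 (highest other 5735). For rolipram against control it was also 1, with 6110 genes (highest other 3741). For rolipram against vehicle 3 of 100 called as many as the real 1906, and the highest other called 2368. Chance division was thus an unlikely source of the gene counts, and none of the other divisions drawn reached the counts against control. Between rolipram and vehicle it was not excluded, since another division called more genes than the real one. Nor was it excluded for the number of lists. For vehicle against control, 25 of 100 divisions called as many as the 20 lists (highest other 25). For rolipram against vehicle, 15 called as many as the 17 (highest other 23), and for rolipram against control 28 as many as the 17 (highest other 22). The other divisions called a median of 15, 13 and 14 lists, so camera at the preset correlation called many lists in a typical division.

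The first pattern weighed was the rise of nuclear-encoded respiratory chain genes under rolipram. Their transcripts are short (median exon length 1696 against 4258 bp for all tested genes), but the median change of 0.41 lay at percentile 100 of 10000 lists matched on length and expression (median 0.16, highest 0.28), and the subunit score exceeded that of matched genes by 0.31 (exact permutation p = 0.00884), which argues against length or abundance as the whole source. Depth stayed open: without the 4 libraries over 29 M reads the median was 0.3356, above 0.2066, its halved value over all libraries, by less than the standard error of 0.1797, with 77 of 79 subunits higher. A milder tumour response as a whole could not be told apart from an effect on these genes: with the atrophy score as covariate, the rolipram difference of 0.43 became 0.2191 (interval -0.145 to 0.583, permutation p = 0.183). The pattern may therefore be a part of a general shift toward control, or specific to respiration, and tumour load was not given in the sources used here.

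The second was the fall of fibroblast and matrix genes with the tumour. The markers did not fall alike: the 7 collagens fell by a median of 1.83 and the 9 other markers by 0.66. The difference of their scores changed by -1.295 (exact permutation p = 0.000583). A smaller share of fibroblasts would lower all these transcripts alike only under 2 conditions. Other cells must not make them, and the fibroblasts lost must resemble those that remain. Neither was tested, so this difference cannot exclude cell share as the source. On scaling to total reads, the list median was -1.225 after median-of-ratios scaling and -1.05 as deposited. That outcome was fixed in advance. The scaling only removed the known upward shift of all genes, whose median went from 0.151 to 0.004, so it could only lower the list. The test therefore adds no support, and a shift upward is opposite in sign to the fall. A lowered activity of collagen genes in the tumour-bearing mice is a hypothesis found on these data, which do not separate it from cell share. Another mix of connective tissue in the sampled piece stays open, as tendon markers fell as well.

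The third was the loss of calls between rolipram and vehicle without the 4 deepest libraries, from 1906 to 607 genes. Removing 2 libraries at random from each group called as few in 39 of 100 draws (median 893.5, range 44 to 2777), so the smaller groups alone may account for it, and no separate effect of depth was seen by this test.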

How the results depend on the processing

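The alternatives leaving out the deepest libraries and the libraries numbered 7 were chosen after the data had been seen. Gene counts stayed within 1.5 times under pseudocounts of 0.1 and 5, without the filter, and without trend and robust moderation. Fewer genes, by construction, were tested with a mean RPKM of at least 5, which left 1404 lower in C26 vehicle and 929 lower in C26 rolipram against controls, where 2646 and 1824 had been. For C26 rolipram against C26 vehicle (1090 higher, 816 lower), a fit of these groups alone gave 467 higher and 300 lower, array weights gave 1379 lower, and leaving out the 4 libraries over 29 M reads gave 255 higher and 352 lower; apart from the smaller number of libraries in the last, the cause was not tested. For C26 rolipram against control, median-of-ratios scaling gave 2964 lower and quantile normalisation 2823, since both remove the shift of all genes. Higher calls were then 50.6% and 51.6% of all calls for C26 vehicle against control (64.6% as deposited), 54.5% and 59.7% for rolipram against vehicle (57.2%), and 49.4% and 52.6% for rolipram against control (70.1%). Leaving out each library gave 665 (without rolipram replicate 1) to 1448 higher and 435 (without rolipram replicate 2) to 1072 lower for rolipram against vehicle. Higher counts were also low without rolipram replicate 2 (679), and lower counts without rolipram replicates 1 (523) and 4 (521). The ranges were 4597 to 4894 higher and 2483 to 2816 lower for vehicle against control, and 3780 to 4481 and 1666 to 1918 for rolipram against control. The libraries of different groups shared only a number: after removing group means, those with the same number had a correlation over 0.1 in 4 of 7 pairs of control and C26 vehicle, 0 of 5 of control and C26 rolipram and 1 of 5 of C26 vehicle and C26 rolipram, and correlated most with each other in 3, 0 and 1 of these. With the number as a replicate block the counts were 4837 higher and 2693 lower, 1246 and 852, and 4193 and 1591. Under the block the macrophage list passed for vehicle against control (adjusted p = 0.0438) and the erythroid list for rolipram against control (0.0219), as did Pde4a (0.022) and Pde4d (0.0483) for rolipram against vehicle and Foxo1 (0.047) for rolipram against control, while the common sarcomere list under rolipram (0.147) and 8 named genes no longer passed; the block changed no other call of these. Camera with an estimated correlation called 0 lists in each comparison, with 2, 1 and 3 lists at an unadjusted p below 0.05. Fry called 25, 13 and 20. The estimated correlations ran from 0.00506 for satellite cell markers to 0.967 for erythroid markers, against the preset of 0.01. They were 0.707 for complex I, 0.815 for the proteasome and 0.283 for atrophy genes. Where the estimate is far above the preset, the preset test gives smaller p-values. The gap between camera and fry was not tested. The direction by fry was opposite to that of camera for cyclic AMP signalling (list median 0.0369, fry adjusted p = 0.0399) and denervation genes (0.553, adjusted p = 0.021) in vehicle against control, and for the common sarcomere in rolipram against control (-0.02986, adjusted p = 0.00966); fry does not subtract the shift of all genes. Of 315 results for named genes none reversed; calls were lost for 9 under median-of-ratios scaling, 15 under quantile normalisation, 20 in the fits of each pair of groups alone, 27 when the least favourable library was left out, 8 with the replicate block, 5 each with array weights and a pseudocount of 5, 3 without the filter and 2 with a pseudocount of 0.1. The 315 include results not called in the main fit, which had no call to lose. Calls were gained for 4 results with array weights, 3 each under median-of-ratios scaling and with the replicate block, 2 under quantile normalisation and 1 with a mean RPKM of at least 5, among them Pde4a under rolipram in 4 of these settings. Small changes could be missed: with independent noise and few changed genes, 52.2% of simulated changes of 0.5 were recovered between rolipram and vehicle. The share was 62.7% in the other comparisons.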

Other observations

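Further gene lists fixed with the others showed mixed or smaller movements. Of 18 denervation and developmental muscle genes, 9 were higher and 5 lower in C26 vehicle than in controls, with a list median of 0.40 above that of all genes, although the camera direction was down without a call (adjusted p = 0.908). Gadd45a, a stress gene induced when nerve supply is lost, rose by 2.55 and the acetylcholine receptor subunit Chrnb1 by 1.22. Under rolipram 5 were higher and 2 lower than in C26 vehicle (camera adjusted p = 0.144, exact permutation adjusted p = 0.0441): the muscle transcription factor Myog rose by 1.01 and Chrnb1 by 0.41, while Musk fell. Against controls 9 were higher and 4 lower (adjusted p = 0.816), and Chrne, the adult receptor subunit, fell by 2.02. Counts adjusted over the list alone were the same in all 3 comparisons. Of 19 genes of the integrated stress and unfolded protein responses, 10 were higher and 2 lower with the tumour (adjusted p = 0.315), 0 changed under rolipram (adjusted p = 0.386), and 13 were higher and 3 lower in C26 rolipram than in controls (adjusted p = 0.113, or 0.0445 after median-of-ratios scaling), the same adjusted over the list alone. Xbp1, a driver of chaperone genes, rose by 1.53 with the tumour and Ppp1r15a, which ends the translation block of the response, by 2.28, whereas Ddit3 fell by 0.87. Of 18 circadian clock genes, 7 were higher and 8 lower with the tumour (adjusted p = 0.357), 3 higher and 2 lower under rolipram (adjusted p = 0.249, or 3 and 3 adjusted over the list alone), and 7 higher and 8 lower in C26 rolipram than in controls (adjusted p = 0.0669). With the tumour the output gene Dbp changed by -3.68 and the repressor Bhlhe41 by -2.06. Under rolipram Rora, an activator of clock genes, fell by 1.05 and Cry1, a core repressor, rose by 0.47.

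Interferon-stimulated genes changed little: of 18 tested, 4 were higher and 3 lower with the tumour (3 and 3 adjusted over the list alone, adjusted p = 0.357), 0 changed under rolipram (adjusted p = 0.23), and 1 was higher and 5 lower in C26 rolipram than in controls (1 and 3 adjusted over the list alone, adjusted p = 0.0705). With the tumour H2-K1, which presents antigen, rose by 0.76, and the guanylate-binding protein Gbp3 fell by 0.46. Among cell-type markers, endothelial genes had 6 of 12 higher and 1 lower with the tumour (adjusted p = 0.478), 0 changed under rolipram (adjusted p = 0.386) and 4 higher and 1 lower against controls (adjusted p = 0.79), the same adjusted over the list alone. Esam, a junction protein, rose by 0.82 with the tumour and Vwf, the platelet-binding factor, by 0.74, while Kdr, the main receptor for vascular growth factor, fell by 1.39. Adipocyte markers had 1 of 8 higher and 2 lower with the tumour (1 and 1 adjusted over the list alone, adjusted p = 0.579), 1 lower under rolipram (adjusted p = 0.202) and 1 higher and 2 lower against controls (adjusted p = 0.192). Plin4, a lipid droplet protein that muscle also makes, rose by 2.14 with the tumour and Car3 fell by 1.88. Schwann cell markers had 1 of 9 higher and 3 lower with the tumour (0 and 1 adjusted over the list alone, adjusted p = 0.0985), 0 changed under rolipram (adjusted p = 0.592) and 1 lower against controls (0 adjusted over the list alone, adjusted p = 0.113), S100b, a call lost without any of 6 libraries, such as rolipram replicate 1 (adjusted p = 0.113). Satellite cell markers had 2 of 4 higher with the tumour, Sdc4 (1.76) and Chrdl2 (0.68) (adjusted p = 0.548), 1 lower under rolipram, Sdc4 (adjusted p = 0.127, exact permutation adjusted p = 0.0441), and 2 higher and 1 lower against controls (adjusted p = 0.972), where the list median lay above that of all genes and the camera direction was down. Smooth muscle and pericyte markers had 1 of 8 higher and 4 lower with the tumour (adjusted p = 0.174), among them Rgs5 (-0.33), 0 changed under rolipram (adjusted p = 0.582) and 2 lower against controls (adjusted p = 0.0629). Counts adjusted over the list alone were the same for the satellite, smooth muscle and remaining adipocyte comparisons. The neutrophil list had only 2 tested genes and no list test: S100a8 and S100a9 rose by 1.59 (0.70 with a pseudocount of 5, which did not pass, adjusted p = 0.0822) and 1.27 with the tumour and by 2.71 and 1.17 in C26 rolipram against controls, and 0 changed under rolipram. No member of the lymphocyte list was in the table, although Ighm, an immunoglobulin gene outside that list, was tested. Of the epithelial or tumour cell markers, 2 were in the table with 0 tested.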
